A study of Oryza sativa with 3 samples.

How the data were processed

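Small RNA was measured in young panicles of japonica rice (Oryza sativa) of 3 genotypes, wild type, ld-1 and ld-2, with 1 library per genotype. Per the labels, total RNA was extracted with Trizol, RNA of 20 to 30 nt was purified from a denaturing gel, libraries were made with the NEXTFlex Small RNA-seq kit v3, and sequencing was on an Illumina MiSeq. The plants grew in a greenhouse or in a field plot, and which of these applied to each sample is not given in the sources used here. The values deposited by the authors are raw read counts, per the file headers, with 1 row per mature miRNA sequence and 1 column per library. Adapter trimming, mapping, the rules of counting (mismatches allowed, reads shared between similar sequences) and the miRNA annotation release are not given in the sources used here.

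The table had 367 rows with 367 different sequences, so no rows were merged, and 90 rows had no read in any library. A sequence encoded at several loci stood as 1 row under joined names, such as miR172a//miR172d. Arms of the precursor were not named in the table, so different sequences under 1 name are told apart here by sequence. Targets stated for a list are those of its families, and opposite-arm sequences in the list need not share them. Genome positions of the miRNA genes were not analysed here.

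Read counts were converted to RPM (reads scaled to library size) and scaled by the trimmed mean of M values (TMM, edgeR 4.0.16 in R 4.3.3), giving factors of 1.02 for wild type, 0.894 for ld-1 and 1.09 for ld-2. Ratios and intervals were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. A feature was tested when it had at least 30 reads summed over the 3 libraries, which kept 109 features holding 99.7% of the reads. A feature was listed as higher or lower when its log2 ratio was at least 1 in size (2-fold) and its exact 95% interval (Clopper-Pearson on both counts, given the scaled library sizes) excluded a ratio of 1. Ratios to a count of 0 were computed against a floor of 3 counts and are bounds that leave out the error of the other count, so the upper 95% limit is given beside them. There are no replicates, so no p-value was computed. Reads are not independent molecules, and the intervals and floors cover counting error only, not the variation between plants.

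Comparisons were ld-1 against wild type, ld-2 against wild type and ld-2 against ld-1. As both mutants share the wild type library, the overlap of their lists was set beside 1000 sets of 3 libraries simulated with counting noise alone, which hold no variation between plants, and beside the product of the list sizes over the features tested. Lists of miRNA families were fixed before the data were examined: miR172; miR156, miR529 and miR535; miR159 and miR319; auxin signalling; meristem and organ patterning; miRNA pathway feedback; miR169; nutrient; copper and laccase; reproductive phasiRNA triggers; and miR444. The median of a list with at least 3 tested members was ranked among 10000 random lists of equal size, matched over 5 bins of expression, as a description of these libraries. Random lists were drawn feature by feature from all tested features, whereas members of a list can vary together. Extreme percentiles may therefore overstate how unusual a list is. The features named were every miR172 sequence, the 10 highest and 10 lowest listed ratios per mutant with at least 100 reads in the higher library, the 10 most abundant features, up to 4 members per list by abundance, and the 5 highest and 5 lowest between the mutants. Features named outside this rule were chosen after their values were seen.

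The listing rule and its intervals were tested on simulated data with the depths of the libraries. Each comparison had 100 runs, with 40 changed features among 109. The percentages that follow are for the rule and the intervals and do not assess the scaling step. The rule listed 45.2% to 47.4% of features set to differ 2-fold, 92.3% to 97.4% of those set to differ 4-fold, and 0.754% to 1.07% of unchanged features, and 96.3% to 96.4% of the intervals held the true ratio. As the listing threshold is itself 2-fold, many features set to differ 2-fold would fall under it at any depth.

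The alternatives were RPM of all miRNA reads, DESeq2 1.42.0 size factors, library sizes without the 5 most abundant features, no minimum or a minimum of 100 summed reads, size thresholds of 1.5-fold and of a log2 ratio of 1.5, a 99% interval, unmerged rows, sums by family and arm, the median of the miR172 members, and 0.5 or 5 reads added to each count. Arms were told apart for this by an edit distance of 8 between sequences. Libraries thinned to 66642 reads, and the counts without miR2118, were added after seeing the data. Rows under the read minimum were left out of the comparisons.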

Results

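Young panicles of wild type rice and of the lodiculeless mutants ld-1 and ld-2 were compared for the levels of mature miRNAs. The series title names a mutation of miR172b as the origin of the lodiculeless spikelet, in which flowers stay closed (cleistogamy). Lodicules are the small organs that swell to open a grass floret. The libraries held 116818 miRNA reads in wild type, 140807 in ld-1 and 66642 in ld-2, and 225, 221 and 221 miRNA sequences had a read. A single read corresponded to 8.37, 7.94 and 13.7 scaled RPM, so ld-2 was measured with the lowest precision. There was 1 library per genotype and no replicate, so differences are given with intervals for counting error and were not tested against the spread between plants. The sequence shared by miR159a and miR159b took 45.4%, 49.4% and 45.5% of the reads, and the 5 most abundant sequences took 78.5%, 79.9% and 73.5%.

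The first question was how the miR172 family, which represses AP2-like transcription factors in floral organ identity and phase change, differed between the genotypes. The mature miR172b sequence GGAATCTTGATGATGCTGCAT had 298 reads in wild type, 2 in ld-1 and 1 in ld-2. Its log2 ratio to wild type was -7.30 in ld-1 (95% interval -10.35 to -5.43) and -7.51 in ld-2 (-12.81 to -5.02), or 157-fold and 182-fold lower. The sequence shared by miR172a and miR172d, AGAATCTTGATGATGCTGCAT, stayed abundant, with 522, 603 and 229 reads. Its log2 ratio was 0.13 in ld-1 (-0.04 to 0.30) and -0.48 in ld-2 (-0.71 to -0.25), neither reaching 2-fold, and the ld-1 value turned negative with RPM of all miRNA reads.

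From miR172a//miR172d to miR172b the sequence differs by A1G, with positions counted from 1 at the 5′ end, and how reads were divided between such close sequences is not given in the sources used here. Of the reads of these 2 sequences, miR172b took 36.3% in wild type (exact 95% binomial interval 33.0% to 39.7%), 0.331% in ld-1 (0.0401% to 1.19%) and 0.435% in ld-2 (0.0110% to 2.40%). The other sequence listed under miR172d, GCAGCACCATCAAGATTCAC, had 115, 80 and 45 reads, with log2 ratios of -0.60 (-1.03 to -0.18) in ld-1 and -0.64 (-1.17 to -0.13) in ld-2. The miR172c sequence TGAATCTTGATGATGCTGCAC had 0 reads in each library, which by the floor of 3 counts allows up to 25.1, 23.8 and 41.2 RPM and by the exact 2-sided 95% Poisson limit up to 30.9, 29.3 and 50.6 RPM. Summed over the family, miR172 had 935, 685 and 275 reads, a log2 ratio of -0.52 (-0.67 to -0.38) in ld-1 and -1.05 (-1.25 to -0.86) in ld-2. The medians of the 3 tested members, -0.60 and -0.64, lay at percentiles 4.05 and 9.96 of random lists.

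**Figure D1:**
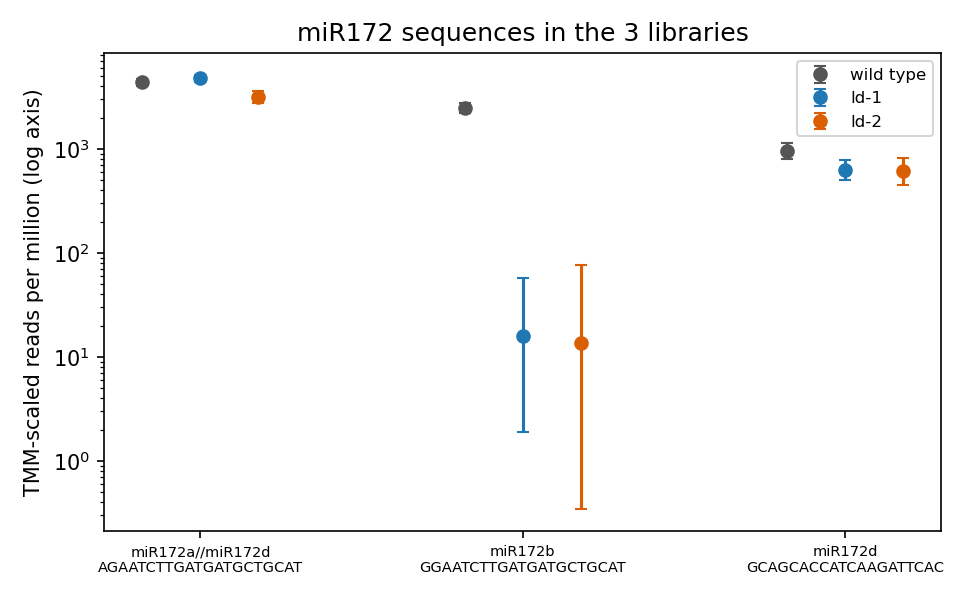
TMM-scaled RPM (log axis) of the 3 miR172 sequences with reads, in the wild type, ld-1 and ld-2 libraries; points are single libraries and bars are exact 95% Poisson intervals for counting error. miR172b stands at 2494 in wild type, 15.9 in ld-1 and 13.7 in ld-2, while miR172a//miR172d stands between 3143 and 4788.

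The comparison of ld-1 with wild type asked which other miRNAs differed in this mutant. Besides miR172b at the low end, the copper and laccase list stood higher: all 5 of its tested members were listed, of which 4 remained with a 99% interval, 3 in thinned libraries or at a minimum of 100 reads, and 1 at a log2 threshold of 1.5. miR528, a monocot miRNA known to target copper proteins such as an ascorbate oxidase, was the most abundant of them. Its sequence TGGAAGGGGCATGCAGAGGAG went from 1885 reads in wild type to 5446 in ld-1, 2.74-fold higher (log2 1.46, 1.38 to 1.53), and its other sequence CCTGTGCTTGCCTCTTCCATT was 2.45-fold higher (log2 1.29, 1.01 to 1.58). miR408 CTGCACTGCCTCTTCCCTGGC, which targets laccases and plantacyanins, was 2.59-fold higher (log2 1.37, 0.78 to 1.99), and miR408 CAGGGATGAGGCAGAGCATGG had 13 and 32 reads (log2 1.22, 0.25 to 2.28).

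In all, 7 of 109 tested features were listed higher and 4 lower in ld-1. Libraries simulated with counting noise alone gave at most 3 higher and 4 lower, and they leave out the variation between plants, so larger counts do not separate genotype from plant. The remaining higher features were miR398b (5 and 21 reads, log2 1.99), which fell under the read minimum in thinned libraries, miR164c, which targets NAC genes (16 and 46 reads, log2 1.45), and miR2878 (11 and 25 reads, log2 1.11). The miR2878 call ended with RPM of all miRNA reads (0.92) and without the 5 most abundant features (1.01, with an interval that included 0). It also ended with a 99% interval and in thinned libraries (1.35). The lower ones beside miR172b were miR2118g (log2 -1.54), miR1873 (log2 -1.02) and miR1861b with its shared copies, which went from 17 reads to 0 and was at least 5.97-fold lower against the floor of 3 counts, with an upper 95% limit of the log2 ratio of -2.12 when the error of both counts is included. The miR2118g call ended with a 99% interval, that of miR1873 with no read minimum (-0.99) and in thinned libraries (-0.87), and that of miR1861b in thinned libraries (-1.50). These 6 features fell outside the naming rule and were chosen after their values were seen.

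The copper and laccase median in ld-1 was 1.37, at percentile 99.95 of random lists. Its tested members were both miR528 sequences, both miR408 sequences and miR398b. Sequences under 1 name may vary together, so the percentile may overstate how unusual the list is. The miR159 and miR319 list, which targets GAMYB and TCP factors, had 4 of 4 members above 0 (miR159f turned below 0 in libraries thinned to equal depth) with a median of 0.41 (percentile 95.6), and miR319b was at 0.51 (0.35 to 0.67). The miRNA pathway feedback list (miR162 and miR168, which target DCL1 and AGO1) had 4 of 4 members below 0 with a median of -0.43 (percentile 2.42), and the miR168a sequence TCGCTTGGTGCAGATCGGGAC was at -0.42 (-0.52 to -0.33). For miR444, which targets MADS-box transcripts, 5 of 5 members were below 0 with a median of -0.57 (percentile 2.27). None of these 3 lists had a member past 2-fold in ld-1. The miR156, miR529 and miR535 list, of families against SPL factors, had a median of -0.21 (percentile 15.9), and its most abundant member, miR535 TGACAACGAGAGAGAGCACGC, was at -0.69 (-0.80 to -0.58). Auxin signalling (median 0.04, percentile 59.6) and meristem and organ patterning (0.03, percentile 61.0) lay near 0, and both medians turned negative with RPM of all miRNA reads and without the 5 most abundant features. The abundant miR166 sequence of the latter list, TCGGACCAGGCTTCATTCCCC, was at -0.07 (-0.10 to -0.03). The reproductive phasiRNA triggers had a median of -0.13 (percentile 23.8) with 1 of 12 listed lower. The 1 tested miR169 sequence, miR169e, was at -0.33 (-0.997 to 0.34). The nutrient families miR395, miR399 and miR827 had 5 reads in wild type, 17 in ld-1 and 10 in ld-2, and none was tested. Their summed reads had a log2 ratio of 1.69 (0.19 to 3.48) in ld-1 and 1.71 (0.03 to 3.61) in ld-2.

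In ld-2, the largest group of differing miRNAs was miR2118, a 22-nt family that triggers phased siRNAs in developing anthers and is a marker of panicle stage and anther tissue. All 12 tested miR2118 sequences were listed higher than in wild type, with log2 ratios from 1.24 to 2.61; at a minimum of 100 reads 6 were listed and the other 6 were not tested. Their list, which includes miR2275 with 1 read in wild type and 0 in both mutants, went from 1293 to 2880 reads, 3.65-fold higher (log2 1.87, 1.77 to 1.97), against a log2 ratio of -0.17 (-0.29 to -0.06) in ld-1. The most abundant, miR2118h//miR2118k TTCCTGATGCCTCTCATTCCTA, had 409, 408 and 914 reads in wild type, ld-1 and ld-2. Each tested miR2118 sequence is 1 or 2 edits from another, so values of single members depend on counting rules not given here. The list median of 1.92 lay at percentile 99.97 of random lists.

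Copper and laccase miRNAs were higher in ld-2 as well, with 4 of 5 members listed and a median of 1.30 (percentile 97.6). miR528 TGGAAGGGGCATGCAGAGGAG was 2.47-fold higher than in wild type (log2 1.30, 1.22 to 1.39) and CCTGTGCTTGCCTCTTCCATT was 3.30-fold higher (log2 1.72, 1.43 to 2.02). Of the 4, 3 remained without the 5 most abundant features or with no read minimum, and 2, the miR528 sequences, with a 99% interval, in thinned libraries and at a minimum of 100 reads. The interval of miR408 CTGCACTGCCTCTTCCCTGGC included 0 (log2 0.53, -0.24 to 1.29). At the low end, the sequence shared by miR156a to miR156j, TGACAGAAGAGAGTGAGCAC, which represses SPL factors, had 458 reads in wild type and 92 in ld-2 and was 3.04-fold lower (log2 -1.60, -1.94 to -1.28), whereas ld-1 had 464 reads.

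Altogether 23 features were listed higher and 8 lower in ld-2. Without miR2118, with scaling recomputed, an alternative added after seeing the data, the counts were 11 and 4. The miR159 and miR319 list had 4 of 4 members below 0 (miR159a//miR159b turned above 0 with RPM of all miRNA reads), a median of -0.87 (percentile 0.94), and miR159f (-1.09) and miR319a (-1.16, -1.89 to -0.48) listed lower, of which miR159f lost its call with RPM of all miRNA reads (-0.998). Its summed reads, dominated by miR159a//miR159b, had a log2 ratio of -0.10, and -0.01 with RPM of all miRNA reads. The more abundant miR319b (513 reads in wild type, against 84 of miR319a) was at -0.65 (-0.89 to -0.41) in ld-2 and was not listed. Arms are not named in the sources used here, so the miR319a ratio need not be that of a TCP-targeting sequence. The SPL-targeting list had a median of -0.50 (percentile 3.89), and miR444d was listed lower (-1.05, -1.56 to -0.57) within a miR444 median of -0.17 (percentile 32.6), a call that ended with RPM of all miRNA reads (-0.95). Auxin signalling had 0 of 9 members listed (median -0.26, percentile 19.4), and meristem and organ patterning had 1 higher and 1 lower of 21 (median -0.17, percentile 7.64), against 0 higher and 3 lower with a median of -0.38 without the 5 most abundant features, and neither call remained with a 99% interval. The feedback list had a median of -0.11 (percentile 52.0), and miR169e was at -0.29 (-1.10 to 0.48).

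**Figure D2:**
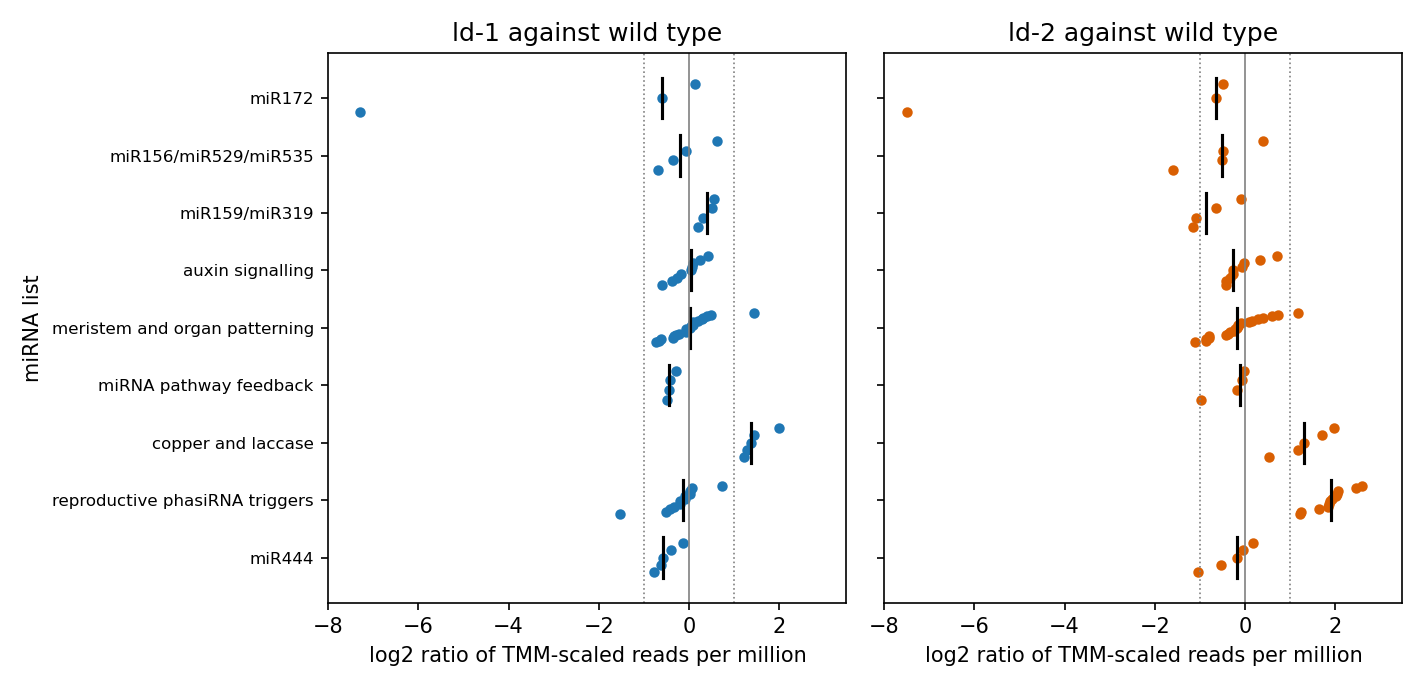
Log2 ratios to wild type of TMM-scaled RPM for the tested members (points, 1 per sequence) of each list with at least 3 tested members, in ld-1 and ld-2; black bars are list medians and dotted lines mark 2-fold. The reproductive phasiRNA triggers stand at a median of -0.13 in ld-1 and 1.92 in ld-2, and copper and laccase at 1.37 and 1.30.

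The mutants were then compared for shared differences. The features listed higher in both were 5: both miR528 sequences, miR408 CAGGGATGAGGCAGAGCATGG, miR398b and miR164c. Without the 5 most abundant features in the library sizes 3 remained, as miR408 (0.98) and miR164c (0.97) no longer reached 2-fold in ld-2. The miR528 sequences were the 2 that remained with a 99% interval and at a minimum of 100 reads, and miR398b was the 1 that remained at a log2 threshold of 1.5. Only miR172b was listed lower in both. With counting noise alone and a shared wild type library, the simulations gave means of 0.079 and 0.029 features (at most 2 and 1), and lists of these sizes drawn independently would share 1.48 and 0.294. Most of the covariance of the log2 ratios across features, 0.547 against 0.0485 in the simulations, came from miR172b: without it the values were 0.0804 and 0.0488. Pearson r across features was 0.46 against 0.436 in the simulations, and 0.111 against 0.436 without miR172b. For the covariance and r, unlike the main ratios, 0.5 reads scaled to library size were added to each count. The ratios of miR172b, with few reads in the mutants, depend on this addition. The simulated r comes from the shared wild type library under counting noise alone, and differences in only 1 mutant, such as miR2118, lower the observed r. The comparison of r therefore cannot show whether the mutants agree more or less than noise would give. Features are not independent replicates, and a chance departure of the 1 wild type library would enter both mutants alike.

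Between the mutants, ld-2 stood higher than ld-1 in 21 features and lower in 6, with 23 and 3 under RPM of all miRNA reads. All 12 miR2118 sequences were among the higher ones (median log2 2.00, sum 2.04, 1.95 to 2.14). Lower in ld-2 were miR319a (log2 -1.71, -2.42 to -1.06), the miR156 sequence (-1.54, -1.88 to -1.22), miR159f (-1.30), miR319b (-1.15), miR166k GGTTTGTTGTCTGGCTCGAGG (-1.12) and miR1428e (-1.33), the last named outside the rule after its value was seen. The calls of miR319b (-0.86), miR166k (-0.83) and miR1428e (-1.04, with an interval that included 0) ended with RPM of all miRNA reads. miR172b, with 2 and 1 reads, could not be compared at this depth (-0.21, -6.09 to 4.05), and miR528 TGGAAGGGGCATGCAGAGGAG was at -0.15 (-0.22 to -0.08), a sign that turned positive with RPM of all miRNA reads. Scaling by all miRNA reads shifted the median of the tested features by -0.19 in ld-1, 0.10 in ld-2 and 0.29 between the mutants, and leaving out the 5 most abundant features shifted it by -0.10, -0.21 and -0.11.

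**Figure D3:**
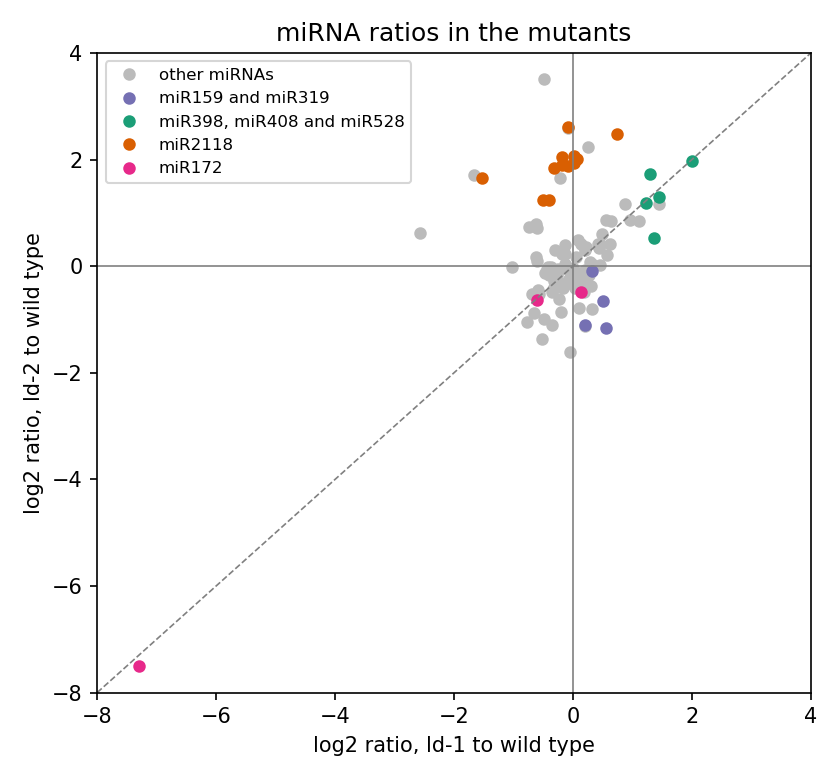
Log2 ratio to wild type in ld-1 (horizontal axis) against ld-2 (vertical axis) for the 109 tested features, 1 point each, with the dashed line at equal ratios. miR172b stands apart at -7.30 and -7.51, the miR2118 points lie between 1.24 and 2.61 on the ld-2 axis, and miR398, miR408 and miR528 lie above 0 on both axes.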

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

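All weighing tests here, and the choice of rows under the read minimum, were chosen after the results were seen.

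The miR2118 list stood 2.00 (median log2 ratio) higher in ld-2 than in ld-1, with medians of opposite sign against wild type, and miR2118g was listed lower in ld-1 and higher in ld-2, a log2 ratio of 3.18 between the mutants, although its ld-1 call (22 and 8 reads) ended with a 99% interval; neither difference was tested against the spread between plants. The scalings tried move all features of a library alike, and they shifted the median of the tested features in ld-2 by -0.21 to 0.10. They could therefore not bring the list median of 1.92 down to 0.866, the upper limit for random lists under the main scaling. The lowest list median over the scalings was 1.71, a result fixed by the sizes of these shifts. It shows that the choice among these scalings did not set the pattern, and is no further evidence on its cause. An effect common to both ld mutants stays open: the ld-1 ratio of the summed miR2118 reads was -0.17 (-0.29 to -0.06), an interval for counting error that cannot exclude it with 1 library per genotype. A different panicle stage or anther content of the ld-2 sample may account for the pattern and stays open too. The other miRNA of the list, miR2275, had 1 read over the libraries and need not vary with miR2118, so it cannot decide this. An effect of the ld-2 genotype is likewise untested with 1 library.

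The miR159 and miR319 list drew attention because its members lay above 0 in ld-1 and below 0 in ld-2, except that miR159a//miR159b turned above 0 in ld-2 with RPM of all miRNA reads and miR159f below 0 in ld-1 in thinned libraries. Its median log2 ratio between the mutants was -1.23, a difference that was not tested.

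Among the 168 rows with reads under the minimum, 1 was at least 2-fold higher in ld-1 with a 99% interval excluding 1, miR11339 with 13 reads against 2 in wild type, and 8 were so in ld-2. These were miR399d (8 reads against 1), miR5486 (17 against 0), miR5487 (18 against 5), miR5488 (10 against 3), miR5494 (7 against 0), miR5507 (19 against 1), miR5516a//miR5516b (15 against 1) and miR5822 (14 against 2). In ld-1, miR399d had 10 reads (log2 3.25, 95% interval 0.43 to 8.69) and miR5507 had 8 (2.92, 0.03 to 8.40). Thus miR399d and miR5507 were not higher in ld-2 alone. In the other direction, 2 rows were lower in both mutants by the same rule. miR1874 TATGGATGGAGGTGTAACCCGATG had 16, 1 and 1 reads in wild type, ld-1 and ld-2, with log2 ratios of -4.08 (95% interval -9.47 to -1.39) and -3.29 (-8.68 to -0.60). miR160c GCGTGCACGGAGCCAAGCATA had 15, 3 and 0 reads, a log2 ratio of -2.40 (95% interval -4.83 to -0.58) in ld-1. In ld-2 it was at least 3.05-fold lower against the floor of 3 counts, with an upper 95% limit of the log2 ratio of -1.13 when the error of both counts is included.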

How the results depend on the processing

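Libraries thinned to equal depth, and the counts without miR2118, were chosen after seeing the data. Of 818 alternative values for 39 named features, 803 kept their side of the threshold, 12 fell under it and 3 passed it. The sign differed from the reported one in 36 of these values, each of a ratio not listed and at most 0.326 in size. The following counts moved by more than 1.5 times; where fewer features, another threshold or less depth did not set the change, the cause was not tested. RPM of all miRNA reads gave 5 lower in ld-2 and 3 lower in ld-2 against ld-1, and leaving out the 5 most abundant features gave 3 higher in both mutants. With no minimum, 13 were higher in ld-1, 13 lower in ld-2, 32 higher in ld-2 against ld-1 and 3 lower in both. At a minimum of 100 reads, ld-1 had 3 higher and 2 lower, ld-2 had 10 and 3, ld-2 against ld-1 had 9 and 3, and 2 were higher in both. A 1.5-fold threshold gave 9 lower in ld-1, 14 in ld-2, 12 in ld-2 against ld-1 and 3 in both. A log2 threshold of 1.5 gave 1 higher in ld-1, 2 lower in ld-2, 2 lower in ld-2 against ld-1 and 1 higher in both, and a 99% interval gave 5 lower in ld-2 and 2 higher in both. Summing by family and arm gave 11 higher in ld-2, 10 higher in ld-2 against ld-1 and 0 lower in both, since miR172b is then summed with the other miR172 sequences. Thinned libraries gave 2 lower in ld-1 and 5 lower in ld-2. Without miR2118, ld-2 had 11 higher and 4 lower, and 10 were higher than in ld-1. The miR172 log2 ratio in ld-2 was -0.64 as the median of members in place of the sum. Unmerged rows moved nothing, as no sequence was repeated. The listed miR408 CAGGGATGAGGCAGAGCATGG fell under 2-fold in 1 random thinning (0.87 in ld-1, 0.92 in ld-2) and, in ld-2, also without the 5 most abundant features (0.98). At the depths of these libraries, 45.2% to 47.4% of features set to differ 2-fold were listed in simulated data. The threshold is itself 2-fold, so many such features would fall under it at any depth.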

Other observations

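The weighing tests and the grouping of rows by name in this part were chosen after the results were seen.

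Beyond the lists, 41 tested features belonged to no family fixed in advance, and 6 of the 23 features higher in ld-2 were among them. These included miR5791 (4, 3 and 28 reads in wild type, ld-1 and ld-2), miR5797 (6, 6 and 22), miR5793 (8, 10 and 23), miR5519 (12, 4 and 24) and miR5806 (11, 10 and 21). Of the 8 rows under the read minimum that were higher in ld-2, 7 had names of the same number range, from the miR5400s to the miR5800s. All 52 rows of 21 nt in this range, summed, had 213, 235 and 380 reads, a log2 ratio of 1.55 (1.30 to 1.80) in ld-2 and 0.07 (-0.21 to 0.34) in ld-1. Because the range was noticed through its highest rows, the sum was repeated without those listed or singled out in ld-2: the remaining 40 rows had 160, 179 and 162 reads, a smaller log2 ratio of 0.73 (0.41 to 1.06) in ld-2. The 11 rows of 24 nt in the range had 40, 34 and 16 reads, with a log2 ratio of -0.61 (-1.54 to 0.26) in ld-2.

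By length, 24-nt rows took 1.88%, 1.80% and 2.36% of the miRNA reads in wild type, ld-1 and ld-2. The 22-nt rows took 7.39%, 7.12% and 9.14%, and 6.28%, 6.27% and 4.82% without miR2118, nearly all of them the 7297, 8795 and 3170 reads of miR1859.

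miR172b stood far lower in both mutants. A difference in library depth is argued against, since ld-1 was deeper than wild type (140807 against 116818 reads), and by the share of miR172b in the reads of miR172b and miR172a//miR172d, whose upper 95% limit in the mutants was at most 2.40%, against a lower limit of 33.0% in wild type. Counting of miR172b reads as miR172a//miR172d stays open. If all had been counted so, the summed reads of both would be level with wild type. The summed log2 ratio was -0.51 (-0.67 to -0.36) in ld-1 and -1.12 (-1.34 to -0.91) in ld-2. These intervals lie below 0 but leave out the variation between plants. Both ratios lay inside the middle 95% of tested features (-1.57 to 1.39 and -1.22 to 2.51). That range cannot decide, because miR172b held only 36.3% of these reads in wild type and its full loss would also stay inside. Reads of an altered miR172b sequence could also have been left uncounted, and 0 rows within 2 edits of miR172b, other than named miR172 sequences, were there to show them. A loss of mature miR172b through the mutation named in the series title is the biological explanation the design gives, and it was not tested apart from these.

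miR528 stood higher in both mutants. A capture or counting bias of 1 sequence is argued against, as the lowest lower limit over both miR528 sequences and both mutants was a log2 ratio of 1.01. Over the scalings tried, the lowest log2 ratio of the abundant sequence was 1.10, so the choice among them did not set the pattern. These scalings move all features of a library alike and by little, so this is no further evidence on its cause. A low value in the 1 wild type library may account for the pattern, as the mutants differed by a log2 ratio of only -0.10 from each other and no second wild type library was analysed here. Growth in a greenhouse or a field, not given per sample, and an effect of the ld genotype also stay open and untested.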
